A study of Mus musculus with 18 samples.

How the data were processed

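The 18 arrays measured total RNA of mouse embryonic fibroblasts on day 6 after retroviral infection with 6 factor combinations, with 3 biological replicates each. RNA was labelled with biotin and hybridized to Affymetrix arrays. The deposited values were used as they stood: they are log2 intensities normalized between arrays by the authors, judged from their range and from nearly equal medians, while the normalization method, the summarization and the base of the logarithm are not given in the sources used here. Differences are therefore differences of the deposited values, read as log2. The number of arrays limits the precision.

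The table held 28856 probes. The annotation gave 1 gene symbol for 21789 probes and several for 1621, and 5446 were not listed. Probes with 1 symbol were used, and for the 998 genes with more than 1 probe the probe with the highest mean over all arrays stood for the gene, which left 19939 genes. No filter on dim genes was applied. Zic3 had no probe with its name and could not be followed.

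A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, and its moderated test was applied to 11 comparisons: each group against OSK, OSKZE against OSKZ, OSKE and OSKZN, OSKE against OSKN, and the interactions of Zic3 with Esrrb and with Nr5a2. P-values were two-sided and adjusted by Benjamini and Hochberg over the genes of a comparison, and a gene passed at an adjusted p under 0.05. Errors of log2 differences are limma's standard errors.

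Gene lists were tested with camera of limma at its preset correlation of 0.01 between genes, with the adjustment over the 26 lists of a comparison, and again with the correlation estimated from the data. The lists were delivered factors, naive pluripotency, fibroblast and mesenchymal, contractile and smooth muscle, epithelial, glycolysis, oxidative phosphorylation, TCA cycle and pyruvate dehydrogenase, fatty acid oxidation, mitochondrial biogenesis regulators, one-carbon and serine metabolism, cholesterol synthesis, hypoxia response, cell cycle, p53 and senescence, interferon response, mesendoderm and primitive streak, extraembryonic endoderm, trophoblast, neural, myeloid, endothelial, skeletal muscle, adipocyte, keratinocyte and cartilage and bone. Of their 604 symbols, 566 were measured, and list sizes in the text count these. For each list the members that passed were counted over all genes and adjusted over the list alone.

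The genes named were chosen by rule. They are the 12 largest rises and 12 largest falls against OSK, or 8 and 8 in the other comparisons, among genes that passed and, for pairwise comparisons, whose groups did not overlap. Predicted genes, gene models and olfactory, vomeronasal and small RNA genes were passed over. Up to 4 members per list that passed, and the factors delivered, were added. From these the text takes by preference genes whose call did not depend on 1 array, a choice made afterwards. Effects of Esrrb and Nr5a2 were correlated across genes, with pairs that share no array and with the pair that shares the OSK arrays beside 100 simulations of unchanged groups.

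The lists, the comparisons, the threshold, the naming rule and the alternatives were fixed before the data were examined, except that leaving out all arrays of replicate number 1, and the list test with both a block and an estimated correlation, were added afterwards. The other settings tried were quantile normalization, leaving out the dimmest 33.3% of genes, all probes of the table, the mean of a gene's probes, trend and robust settings of the moderation, only the arrays of the groups compared, the replicate number as a block, and each array left out in turn. In simulated data, 80% and 92% of changes of 0.5 and 1 (log2) were recovered for OSKZE against OSK. Of the called genes, 5.61% were unchanged. For the interaction of Zic3 and Esrrb these were 46%, 88% and 7.39%. A raised list was called and 0 of 25 unchanged lists, which says little of real lists whose genes may move together.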

Results

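RNA was measured in mouse embryonic fibroblasts (MEFs) that had received transcription factors by retrovirus and were collected on day 6. Every group received Pou5f1 (Oct4), Sox2 and Klf4, together called OSK, the factors that turn fibroblasts into induced pluripotent stem cells. The 6 groups were OSK alone, OSK with Zic3 (OSKZ), with Esrrb (OSKE), with Nr5a2 (OSKN), with Zic3 and Esrrb (OSKZE) and with Zic3 and Nr5a2 (OSKZN). Each group had 3 biological replicates on Affymetrix whole-transcript arrays, 18 arrays in total, whose number limits the precision. The deposited log2 values ran from 4.48 to 14.37, with array medians between 7.97 and 8.03. Over 19939 genes, arrays of the same group correlated at a median Pearson r of 0.991 (lowest 0.987), and arrays of different groups at a median of 0.981. Genes are not independent replicates. Values below are log2 differences ± SE from limma with 3 arrays per group (n = 3), and for every gene named among the largest changes of a pairwise comparison all 3 values of the higher group lay above all 3 of the other. An exact test of 3 arrays against 3 cannot go below p = 0.1, so the calls rest on limma's test, which shares its error estimate among genes.

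Arrays with the same replicate number moved together across groups. After the group means were taken out, the 45 pairs of arrays with the same number correlated at a median of 0.552 (lowest 0.12), and the 90 pairs with different numbers at a median of -0.473. Among the 18 arrays, 15 correlated best with an array of their own number. Xist, the RNA expressed from an inactive X chromosome, averaged 11.66 ± 0.12, 5.87 ± 0.11 and 5.87 ± 0.0897 in numbers 1, 2 and 3 (mean ± SD over 6 arrays). Of the genes on the Y chromosome, Eif2s3y averaged 5.51 ± 0.076, 10.09 ± 0.12 and 10.08 ± 0.11 in the same order and Kdm5d 6.3 ± 0.16, 9.32 ± 0.22 and 9.33 ± 0.13. The smooth muscle gene Tagln averaged 11.45 ± 0.23, 10.08 ± 0.53 and 9.89 ± 0.62, and the pluripotency gene Nr0b1 8.24 ± 1.25, 10.34 ± 1.25 and 10.34 ± 1.3. For this reason each comparison was also fitted with a replicate block, which pairs arrays by their number, and its counts over all genes are given where they differ by over 1.5 times. Beside lists that pass only with the block, a p with both is that with the block and an estimated correlation.

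Esrrb read 6.74 ± 0.24 in OSK (mean ± SD, n = 3), 12.2 ± 0.23 in OSKE and 12.25 ± 0.2 in OSKZE. Nr5a2 read 6.96 ± 0.1 in OSK, 12.52 ± 0.16 in OSKN and 12.5 ± 0.2 in OSKZN. Pou5f1 stayed near 13.21 and Klf4 near 10.84 in every group, with no difference from OSK past the threshold. Sox2, delivered to every group, read 7.58 to 7.8 in OSK, OSKZ, OSKE and OSKN, below the array medians, so its delivery was not visible on its probe. No probe named for Zic3 was present, so the delivery of Zic3 was not analysed here. Nr5a2 also rose by 1.25 ± 0.19 in OSKZE, which received no Nr5a2 (adjusted p = 0.00024), and in OSKZ its difference of 0.33 ± 0.19 passed only with the replicate block (adjusted p = 0.42, 0.039 with the block). Esrrb rose by 1.3 ± 0.39 in OSKZN, which received no Esrrb (adjusted p = 0.036), with paired differences of 0.41, 1.24 and 2.26, and this call was lost without OSK replicate 1, OSK replicate 2, OSKZN replicate 2, OSK replicate 3 and OSKZN replicate 3 (adjusted p = 0.114, 0.0894, 0.0903, 0.0642 and 0.148) and with only the 6 arrays of these groups (adjusted p = 0.196). With the replicate block Esrrb passed in OSKZN (adjusted p = 0.0031). Sox2 rose by 1.28 ± 0.44 in OSKZE (adjusted p = 0.049), with paired differences of 0.3, 1.34 and 2.2, and lost its call without OSK replicate 1, OSK replicate 2, OSKZE replicate 2, OSK replicate 3 and OSKZE replicate 3 (adjusted p = 0.147, 0.0851, 0.143, 0.086 and 0.245), over all probes of the table (adjusted p = 0.0586), with trend and robust settings (adjusted p = 0.0532) and with only the 6 arrays of these groups (adjusted p = 0.172). Sox2 in OSKZE passed with the replicate block (adjusted p = 0.0021). The list of delivered factors holds the added gene itself, so its test restates the delivery wherever Esrrb or Nr5a2 was added.

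**Figure D1:**
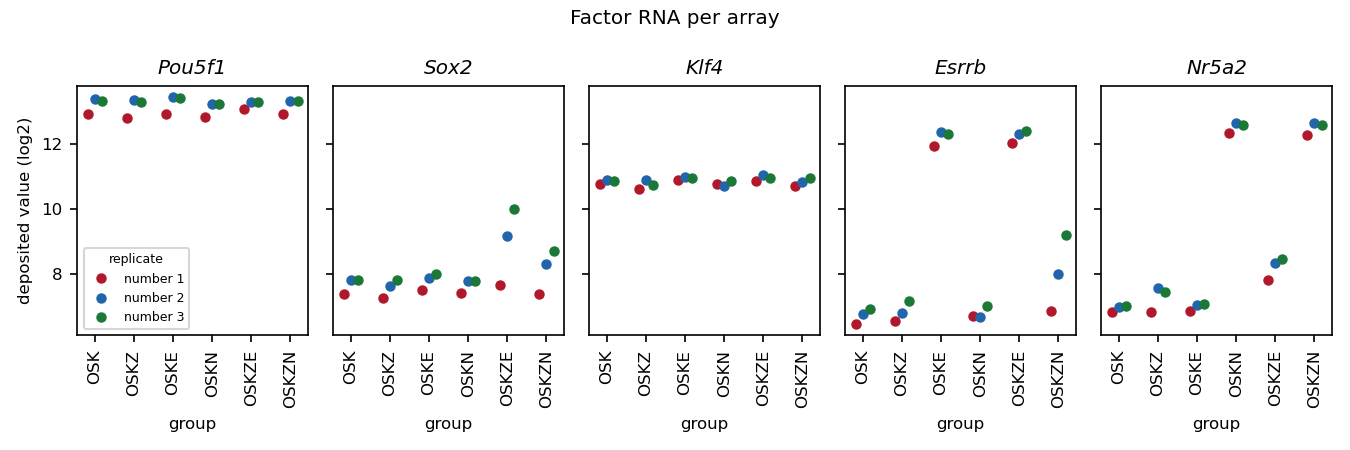
Deposited log2 value (y axis) of Pou5f1, Sox2, Klf4, Esrrb and Nr5a2 in the 6 groups (x axis), 1 point per array, coloured by replicate number. The Esrrb points of OSKE and OSKZE lay near 12.2 against 6.74 in OSK, and those of OSKZN spread with a SD of 1.16.

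The OSKZ and OSK arrays show what Zic3, a zinc finger factor expressed in pluripotent cells, changed when added to OSK. Among the largest rises was that of Slc38a5 (3.38 ± 0.5, adjusted p = 0.0014), a carrier of glutamine and other amino acids, and Far2 (2.33 ± 0.2), Fgf1 (2.3 ± 0.39) and Foxc2 (2.09 ± 0.29) rose as well. The glucose carrier Slc2a3 (1.67 ± 0.16) and the glycolytic enzyme Pfkp (1.02 ± 0.18) also rose. Among the falls were the milk and secretory genes Csn1s1 (-3.07 ± 0.5), Ltf (-2.08 ± 0.31) and Defb1 (-1.83 ± 0.19), the steroid-metabolizing Akr1c18 (-2.39 ± 0.35) and the embryonic globin Hbb-y (-2.09 ± 0.26). The pluripotency factor Nanog rose by 2.53 ± 0.56 (adjusted p = 0.018), a call lost without OSK replicate 1, OSK replicate 2, OSKZ replicate 2 and OSKZ replicate 3 (adjusted p = 0.0783, 0.0555, 0.0765 and 0.105), and also with only the 6 arrays of both groups (adjusted p = 0.106). Tfcp2l1, which maintains the naive state, fell by 1.61 ± 0.4 (adjusted p = 0.036), a call lost without OSKZ replicate 1, OSK replicate 2, OSK replicate 3 and OSKZ replicate 3 (adjusted p = 0.104, 0.143, 0.122 and 0.0752) and with only those 6 arrays (adjusted p = 0.12). In all, 841 of 19939 genes passed limma's test, 452 higher and 389 lower, and 4566 genes (22.9%, with 10% by chance) did not overlap between the groups. That count was 2533 with the replicate block, 459 with only the arrays of the groups compared and 2616 with all 6 arrays of number 1 left out. It became 352 without OSK replicate 2, 497 without OSKZ replicate 2, 469 without OSK replicate 3 and 304 without OSKZ replicate 3.

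Among 77 oxidative phosphorylation genes, 1 rose (0 adjusted over the list alone), 0 fell and 76 did not pass. Averaging 0.077, they had adjusted p = 8.88e-05, and adjusted p = 0.802 with an estimated correlation. The 30 cell cycle genes, 0 of which passed (0 adjusted over the list alone), averaged 0.11 (adjusted p = 0.0176, and adjusted p = 0.832 with an estimated correlation), and the call was lost without OSK replicate 1, OSKZ replicate 2 and OSK replicate 3 (adjusted p = 0.2, 0.408 and 0.0687). The 25 interferon response genes, 0 of which passed (0 adjusted over the list alone), averaged -0.47 (adjusted p = 0.0146, and adjusted p = 0.832 with an estimated correlation), and the call was lost without OSK replicate 1, OSK replicate 2 and OSKZ replicate 2 (adjusted p = 0.2, 0.146 and 0.405). The 38 fibroblast and mesenchymal genes, 0 of which passed (0 adjusted over the list alone, 2 higher and 9 lower with the block), averaged -0.13 (adjusted p = 0.0307, and adjusted p = 0.857 with an estimated correlation), and the call was lost without OSK replicate 1, OSKZ replicate 2 and OSKZ replicate 3 (adjusted p = 0.6, 0.246 and 0.147). Among 23 glycolysis genes, 3 rose (3 adjusted over the list alone), among them Slc2a3 (1.67 ± 0.16) and Pfkp (1.02 ± 0.18), 0 fell and 20 did not pass. Averaging 0.29, they had adjusted p = 0.0549, and adjusted p = 0.832 with an estimated correlation or 0.0145 with the replicate block, adjusted p = 0.809 with both. With the replicate block the myeloid list also passed (mean -0.27, adjusted p = 0.0725, 0.00111 with the block, adjusted p = 0.809 with both). The interferon response mean was -0.19, -1.4 and 0.17 in replicate numbers 1, 2 and 3.

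Esrrb is an orphan nuclear receptor that activates genes of energy metabolism and of the naive pluripotent state, and OSKE against OSK gave its effect in the absence of Zic3. Beside Esrrb itself, large rises were those of Ucp1 (3.9 ± 0.45, adjusted p = 0.00012), Tnni3 (3.82 ± 0.36) and Tmem255a (3.49 ± 0.56), of which Ucp1 uncouples respiration in brown fat and Tnni3 is a cardiac troponin. Frzb (3.16 ± 0.22) and Car2 (3.09 ± 0.43) rose as well, Frzb being a Wnt antagonist. Falls included Ifitm6 (-2.3 ± 0.31), Entpd1 (-2 ± 0.16), Dpp4 (-1.95 ± 0.36) and Cnmd (-1.93 ± 0.36) and the epidermal and epithelial genes Tfap2a (-1.75 ± 0.36), Ehf (-1.71 ± 0.22) and Dsp (-1.58 ± 0.25). Altogether, 2160 of 19939 genes passed limma's test, 1035 higher and 1125 lower, and 6298 genes (31.6%, with 10% by chance) did not overlap between the groups. That count was 4398 with the replicate block, 1238 with only the arrays of the groups compared and 4364 with all 6 arrays of number 1 left out. It became 1037 without OSK replicate 2, 1167 without OSKE replicate 2, 1342 without OSK replicate 3 and 1209 without OSKE replicate 3.

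Of 77 oxidative phosphorylation genes, 13 rose (18 adjusted over the list alone), among them Cox5a (0.61 ± 0.09) and Cyc1 (0.26 ± 0.04), 0 fell and 64 did not pass. Their mean of 0.11 had adjusted p = 7.6e-06, and adjusted p = 0.154 with an estimated correlation. Of 18 fatty acid oxidation genes, 7 rose (10 adjusted over the list alone), among them Slc25a20 (1.16 ± 0.15) and Hadhb (0.56 ± 0.08), 0 fell and 11 did not pass. Averaging 0.23, they had adjusted p = 3.62e-05, and adjusted p = 0.154 with an estimated correlation. Of 18 TCA cycle and pyruvate dehydrogenase genes, 5 rose (5 adjusted over the list alone), among them Mpc1 (0.77 ± 0.11) and Idh2 (0.57 ± 0.06), 0 fell and 13 did not pass. Their mean of 0.16 had adjusted p = 0.028, and adjusted p = 0.514 with an estimated correlation, and the call was lost without OSK replicate 1, OSKE replicate 2, OSK replicate 3 and OSKE replicate 3 (adjusted p = 0.0561, 0.112, 0.0665 and 0.0689).

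Of 30 cell cycle genes, 20 fell (24 adjusted over the list alone), among them Foxm1 (-0.44 ± 0.08), 0 rose and 10 did not pass. Averaging -0.33, they had adjusted p = 2.7e-15, and adjusted p = 0.154 with an estimated correlation. Of 13 one-carbon and serine metabolism genes, 3 fell (5 adjusted over the list alone), among them Tyms (-0.4 ± 0.09), 0 rose and 10 did not pass. Their mean of -0.22 had adjusted p = 0.00118, and adjusted p = 0.0923 with an estimated correlation. Of 25 interferon response genes, 2 fell (4 adjusted over the list alone), 0 rose and 23 did not pass. Averaging -0.89, they had adjusted p = 6.82e-06, and adjusted p = 0.651 with an estimated correlation. Of 38 fibroblast and mesenchymal genes, 3 fell (3 adjusted over the list alone), among them Col6a2 (-0.78 ± 0.12) and Col6a1 (-0.69 ± 0.15), 1 rose and 34 did not pass. Their mean of -0.22 had adjusted p = 0.0254, and adjusted p = 0.877 with an estimated correlation, and the call was lost without OSK replicate 1, OSKE replicate 2 and OSKE replicate 3 (adjusted p = 0.382, 0.112 and 0.0833). Of 13 mesendoderm and primitive streak genes, 1 rose (1 adjusted over the list alone), namely Gsc (0.94 ± 0.14), 0 fell and 12 did not pass. Averaging 0.18, they had adjusted p = 0.028, and adjusted p = 0.641 with an estimated correlation, and the call was lost without OSK replicate 1, OSKE replicate 1 and OSK replicate 2 (adjusted p = 0.0627, 0.169 and 0.0538). The myeloid list did not pass (mean -0.14, adjusted p = 0.316), though Itgam (-1.17 ± 0.16) and Laptm5 (-1.04 ± 0.23) of its 17 genes fell. With the replicate block 3 more lists passed, contractile and smooth muscle (mean -0.11, adjusted p = 0.359, 0.034 with the block, adjusted p = 0.522 with both), epithelial (mean -0.25, adjusted p = 0.139, 0.0315 with the block, adjusted p = 0.731 with both) and trophoblast (mean -0.24, adjusted p = 0.0707, 0.034 with the block, adjusted p = 0.46 with both), and of the contractile genes Des (0.89 ± 0.18) rose.

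Nr5a2, the liver receptor homologue, drives steroid and bile acid genes and can replace Pou5f1 in reprogramming. The OSKN against OSK comparison asked what it changed without Zic3. The steroid-making enzyme Cyp11a1 (5.04 ± 0.26, adjusted p = 2.6e-08) rose most after Nr5a2 itself, with the steroid-converting Akr1c14 (4.02 ± 0.36) and Akr1cl (3.5 ± 0.2) next. Rises also included Pcp4 (3.22 ± 0.25), Pla1a (3.13 ± 0.15), Pcsk1 (3.01 ± 0.47) and Neurog3 (2.93 ± 0.1), Pcsk1 and Neurog3 being genes of hormone-secreting cells. Sh3rf2 (-2.76 ± 0.35), Ltf (-2.28 ± 0.31), Tgm3 (-2.05 ± 0.2), Ehf (-1.95 ± 0.22) and Dsp (-1.85 ± 0.25) fell, Tgm3, Ehf and Dsp being genes of epidermis and other epithelia. For Nr5a2, 1580 of 19939 genes passed limma's test, 895 higher and 685 lower, and 4324 genes (21.7%, with 10% by chance) did not overlap between the groups. That count was 3413 with the replicate block, 1048 with only the arrays of the groups compared and 4070 with all 6 arrays of number 1 left out. It became 827 without OSK replicate 2, 951 without OSKN replicate 2, 917 without OSK replicate 3 and 998 without OSKN replicate 3.

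Among 30 cell cycle genes, 16 fell (25 adjusted over the list alone), among them Bub1b (-0.58 ± 0.11) and Mki67 (-0.49 ± 0.08), 0 rose and 14 did not pass. Their mean of -0.34 had adjusted p = 2.8e-16, and adjusted p = 0.226 with an estimated correlation. Among 18 fatty acid oxidation genes, 5 rose (8 adjusted over the list alone), among them Acadm (0.49 ± 0.07) and Echs1 (0.41 ± 0.07), 0 fell and 13 did not pass. Averaging 0.16, they had adjusted p = 9.03e-05, and adjusted p = 0.226 with an estimated correlation. Among 77 oxidative phosphorylation genes, 3 rose (0 adjusted over the list alone), 0 fell and 74 did not pass. Their mean of 0.076 had adjusted p = 1.9e-05, and adjusted p = 0.226 with an estimated correlation. Among 17 contractile and smooth muscle genes, 1 rose (1 adjusted over the list alone), namely Des (1.18 ± 0.18), 0 fell and 16 did not pass. Averaging 0.3, they had adjusted p = 0.0353, and adjusted p = 0.919 with an estimated correlation, and the call was lost without OSKN replicate 1, OSK replicate 2 and OSK replicate 3 (adjusted p = 0.155, 0.136 and 0.189). Only with the replicate block did 1 more list pass, extraembryonic endoderm (mean 0.23, adjusted p = 0.0639, 0.0412 with the block, adjusted p = 0.578 with both), in which Lama1 (1.23 ± 0.24) rose.

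OSKZE received both Zic3 and Esrrb, the combination named in the title of the series. Against OSK, the largest rises other than that of Esrrb were Ceacam2 (4.65 ± 0.7, adjusted p = 0.00025), Car2 (4.41 ± 0.43), Slc38a5 (3.83 ± 0.5) and Nptx1 (3.82 ± 0.36), and the Wnt antagonist Notum (3.57 ± 0.18) and Ucp1 (3.36 ± 0.45) rose as well. The pluripotency factor Nanog (3.4 ± 0.56, adjusted p = 5e-04) rose in all 3 pairs. Tfap2c (2.55 ± 0.32) and Sfn (2.09 ± 0.16) also rose, Tfap2c being a factor of naive cells, germ cells and trophoblast. The matrix genes Fmod (-2.95 ± 0.36), Ogn (-2.82 ± 0.59) and Adamts5 (-3.02 ± 0.48) fell, together with Shisa3 (-3.55 ± 0.33), Csn1s1 (-3.38 ± 0.5) and C1s1 (-3.11 ± 0.14). Of all comparisons against OSK this had the most calls: 4559 of 19939 genes passed limma's test, 2236 higher and 2323 lower, and 7127 genes (35.7%, with 10% by chance) did not overlap between the groups.

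Of 36 naive pluripotency genes, 17 rose (19 adjusted over the list alone), among them Nanog (3.4 ± 0.56) and Gbx2 (1.13 ± 0.13), 1 fell and 18 did not pass. Their mean of 0.86 had adjusted p = 2.02e-05, and adjusted p = 0.532 with an estimated correlation. In OSKZ, OSKE and OSKN the naive pluripotency list did not pass (mean 0.12, 0.058 and 0.0102, adjusted p = 0.573, 0.772 and 0.871). Of 33 epithelial genes, 7 rose (7 adjusted over the list alone), among them Esrp2 (1.28 ± 0.21), 0 fell and 26 did not pass. Averaging 0.45, they had adjusted p = 0.0083, and adjusted p = 0.726 with an estimated correlation, and the call was lost without OSKZE replicate 3 (adjusted p = 0.226). Of 38 fibroblast and mesenchymal genes, 24 fell (27 adjusted over the list alone), among them Pdgfrb (-1.94 ± 0.41) and Fap (-1.79 ± 0.23), 1 rose, Meox1 (1.91 ± 0.19), and 13 did not pass. Their mean of -0.7 had adjusted p = 3.56e-11, and adjusted p = 0.479 with an estimated correlation. Of 17 contractile and smooth muscle genes, 3 fell (3 adjusted over the list alone), among them Myocd (-0.76 ± 0.12), 0 rose and 14 did not pass. Averaging -0.48, they had adjusted p = 0.0104, and adjusted p = 0.652 with an estimated correlation, and the call was lost without OSK replicate 1 (adjusted p = 0.156).

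Of 77 oxidative phosphorylation genes, 43 rose (54 adjusted over the list alone), among them Cox5a (0.78 ± 0.09), Sdhd (0.38 ± 0.06) and Cyc1 (0.36 ± 0.04), 0 fell and 34 did not pass. Their mean of 0.21 had adjusted p = 3.36e-13, and adjusted p = 0.0411 with an estimated correlation. Of 18 TCA cycle and pyruvate dehydrogenase genes, 10 rose (11 adjusted over the list alone), among them Idh2 (0.64 ± 0.06) and Fh1 (0.49 ± 0.06), 0 fell and 8 did not pass. Averaging 0.25, they had adjusted p = 2.09e-05, and adjusted p = 0.189 with an estimated correlation. Of 18 fatty acid oxidation genes, 10 rose (11 adjusted over the list alone), among them Slc25a20 (0.97 ± 0.15) and Hadhb (0.46 ± 0.08), 0 fell (1 adjusted over the list alone) and 8 did not pass. Their mean of 0.2 had adjusted p = 0.00167, and adjusted p = 0.422 with an estimated correlation. Of 23 glycolysis genes, 13 rose (15 adjusted over the list alone), among them Slc2a3 (2.75 ± 0.16) and Ldhb (2.12 ± 0.23), 3 fell and 7 did not pass. Averaging 0.7, they had adjusted p = 8.08e-05, and adjusted p = 0.479 with an estimated correlation. Of 18 hypoxia response genes, 10 rose (11 adjusted over the list alone), among them Ndrg1 (1.78 ± 0.32) and Pdk1 (1.73 ± 0.33), 0 fell and 8 did not pass. Their mean of 0.82 had adjusted p = 3.73e-05, and adjusted p = 0.48 with an estimated correlation. Of 13 one-carbon and serine metabolism genes, 5 rose (8 adjusted over the list alone), among them Shmt1 (0.73 ± 0.07), 0 fell and 8 did not pass. Averaging 0.32, they had adjusted p = 0.00686, and adjusted p = 0.167 with an estimated correlation. Oxidative phosphorylation was the only list against OSK whose call held with an estimated correlation, and with both the block and an estimated correlation it did not (adjusted p = 0.159).

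Of 30 cell cycle genes, 9 rose (12 adjusted over the list alone), among them Cdc20 (0.87 ± 0.15) and E2f1 (0.82 ± 0.11), 1 fell and 20 did not pass. Their mean of 0.23 had adjusted p = 0.000143, and adjusted p = 0.493 with an estimated correlation. Of 25 interferon response genes, 5 fell (5 adjusted over the list alone), among them Gbp3 (-1.68 ± 0.37), 0 rose and 20 did not pass. Averaging -1, they had adjusted p = 6.61e-05, and adjusted p = 0.652 with an estimated correlation. Of 17 myeloid genes, 2 fell (2 adjusted over the list alone), among them Itgam (-1.26 ± 0.16) and Laptm5 (-0.9 ± 0.23), 0 rose and 15 did not pass. Their mean of -0.43 had adjusted p = 0.0149, and adjusted p = 0.659 with an estimated correlation, and the call was lost without OSK replicate 1 (adjusted p = 0.226).

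**Figure D2:**
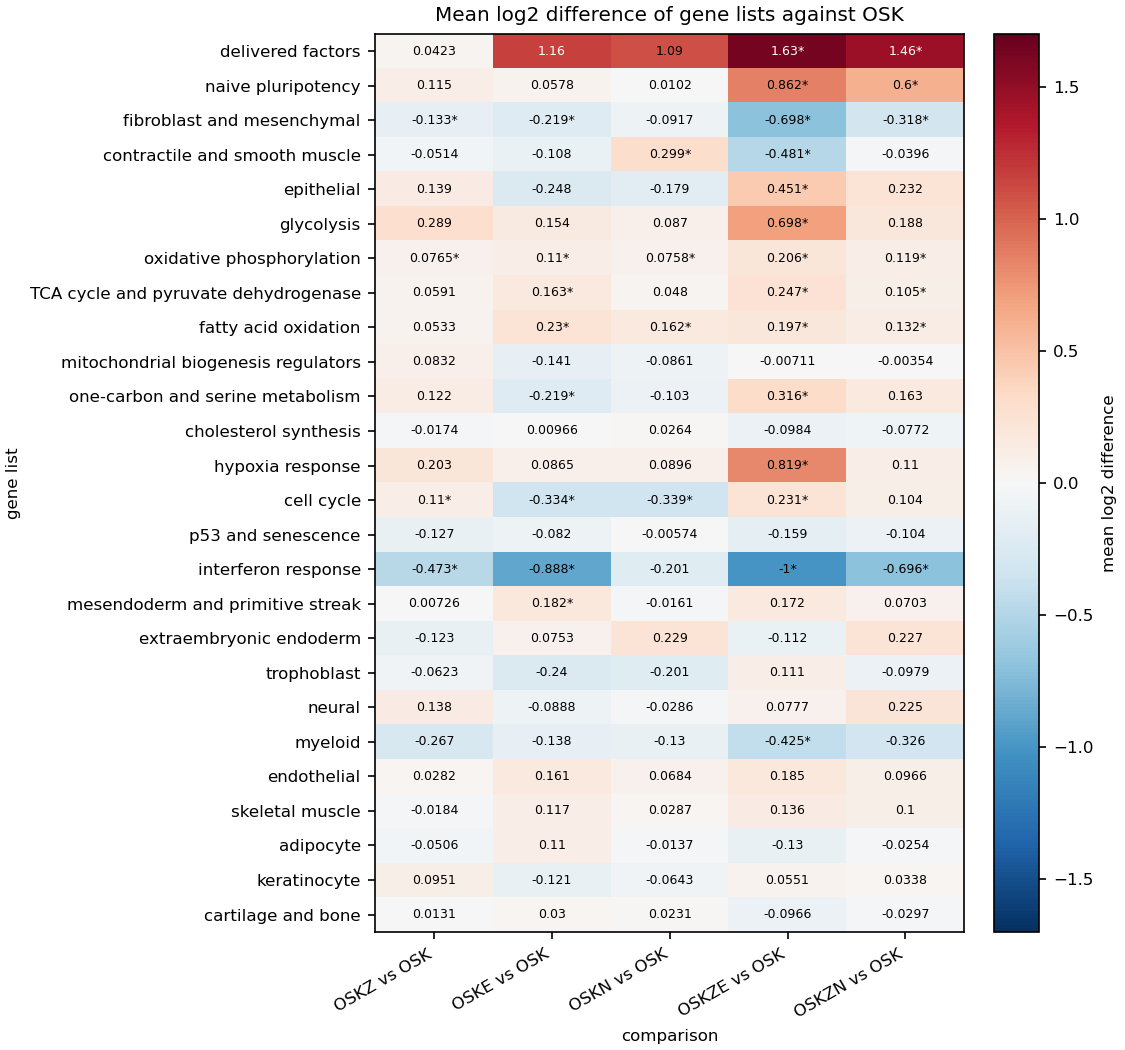
Mean log2 difference of the members of each of the 26 gene lists (y axis) in the 5 comparisons against OSK (x axis), printed and coloured per cell, with an asterisk for an adjusted p under 0.05 at the preset correlation. The oxidative phosphorylation row was positive in all 5 comparisons, from 0.076 in OSKN to 0.21 in OSKZE.

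OSKZN paired Zic3 with Nr5a2, the combination to set beside OSKZE. Cyp11a1 (3.84 ± 0.26, adjusted p = 5.9e-07), Akr1c14 (3.63 ± 0.36) and Cyp2s1 (3.53 ± 0.25) rose together with Slc38a5 (3.47 ± 0.5), Far2 (3.23 ± 0.2) and Lamp5 (3.36 ± 0.27), which had risen in OSKZ, and with the secreted phospholipase Pla2g2a (3.39 ± 0.18). The pluripotency factors Nanog (2.98 ± 0.56) and Sall4 (2.24 ± 0.49) rose, as did Slc2a3 (2.37 ± 0.16). Ifitm6 (-2.79 ± 0.31), Ltf (-2.67 ± 0.31), Sh3rf2 (-2.53 ± 0.35), Shisa3 (-2.5 ± 0.33) and Dkk2 (-2.26 ± 0.3) were among the largest falls. Against OSK, 2748 of 19939 genes passed limma's test, 1461 higher and 1287 lower, and 6013 genes (30.2%, with 10% by chance) did not overlap between the groups. That count was 4972 with the replicate block and 5080 with all 6 arrays of number 1 left out. It became 1655 without OSK replicate 2, 1788 without OSKZN replicate 2 and 1468 without OSKZN replicate 3.

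Among 36 naive pluripotency genes, 8 rose (12 adjusted over the list alone), among them Nanog (2.98 ± 0.56) and Sall4 (2.24 ± 0.49), 3 fell and 25 did not pass. Averaging 0.6, they had adjusted p = 0.00306, and adjusted p = 0.752 with an estimated correlation, and the call was lost without OSKZN replicate 3 (adjusted p = 0.0789). Among 38 fibroblast and mesenchymal genes, 5 fell (6 adjusted over the list alone), among them Col6a3 (-1.06 ± 0.21) and Col6a1 (-0.83 ± 0.15), 2 rose and 31 did not pass. Their mean of -0.32 had adjusted p = 0.000188, and adjusted p = 0.752 with an estimated correlation. Among 25 interferon response genes, 1 fell (0 adjusted over the list alone), 0 rose and 24 did not pass. Averaging -0.7, they had adjusted p = 0.00142, and adjusted p = 0.752 with an estimated correlation, and the call was lost without OSKZN replicate 2 (adjusted p = 0.213). The interferon response mean of OSKZN was -0.15, -1.96 and 0.019 in numbers 1, 2 and 3. Paired by number, the myeloid list passed too (mean -0.33, adjusted p = 0.071, 0.00652 with the block, adjusted p = 0.705 with both).

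Among 77 oxidative phosphorylation genes, 14 rose (22 adjusted over the list alone), among them Sdhd (0.29 ± 0.06) and Ndufb6 (0.3 ± 0.06), 0 fell and 63 did not pass. Their mean of 0.12 had adjusted p = 1.8e-06, and adjusted p = 0.387 with an estimated correlation. Among 18 TCA cycle and pyruvate dehydrogenase genes, 4 rose (6 adjusted over the list alone), among them Idh2 (0.41 ± 0.06), 0 fell and 14 did not pass. Averaging 0.11, they had adjusted p = 0.0299, and adjusted p = 0.752 with an estimated correlation or 0.0663 with the replicate block, and the call was lost without OSK replicate 1, OSKZN replicate 1 and OSK replicate 3 (adjusted p = 0.0701, 0.0952 and 0.0593). Among 18 fatty acid oxidation genes, 6 rose (7 adjusted over the list alone), among them Echs1 (0.43 ± 0.07) and Etfa (0.44 ± 0.07), 1 fell and 11 did not pass. Their mean of 0.13 had adjusted p = 0.0238, and adjusted p = 0.752 with an estimated correlation, and the call was lost without OSK replicate 1 and OSKZN replicate 1 (adjusted p = 0.0617 and 0.0962).

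**Figure D3:**
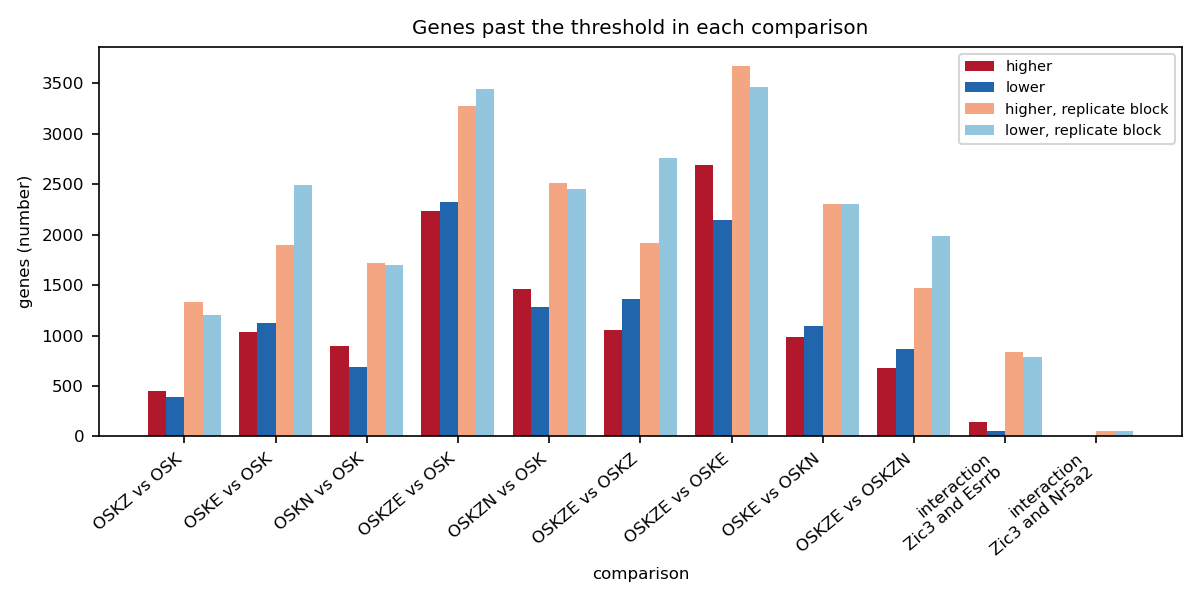
Number of genes past the threshold (y axis) in the 11 comparisons (x axis), with bars for higher and lower genes and paler bars for the fit with the replicate block. The interaction of Zic3 and Nr5a2 had 10 genes, that of Zic3 and Esrrb 191, and OSKZE vs OSKE 4840.

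OSKZE against OSKZ gave the effect of Esrrb where Zic3 was present. Ceacam2 (3.89 ± 0.7, adjusted p = 0.0023), Car2 (3.87 ± 0.43) and Ucp1 (3.51 ± 0.45) rose, as did the naive-state factor Tfcp2l1 (2.49 ± 0.4), a known target of Esrrb. Fmod (-2.54 ± 0.36) and Cnmd (-2.4 ± 0.36) fell, both being matrix genes of tendon and cartilage. Between these groups, 2423 of 19939 genes passed limma's test, 1059 higher and 1364 lower, and 5354 genes (26.9%, with 10% by chance) did not overlap between the groups. That count was 4678 with the replicate block, 903 with only the arrays of the groups compared and 5220 with all 6 arrays of number 1 left out. It became 1457 without OSKZ replicate 2, 1130 without OSKZE replicate 2, 1521 without OSKZ replicate 3 and 1258 without OSKZE replicate 3.

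Of 36 naive pluripotency genes, 14 rose (18 adjusted over the list alone), among them Tfcp2l1 (2.49 ± 0.4), 1 fell and 21 did not pass. Averaging 0.75, they had adjusted p = 4.26e-07, and adjusted p = 0.43 with an estimated correlation. Of 38 fibroblast and mesenchymal genes, 18 fell (26 adjusted over the list alone), 1 rose, Meox1 (1.9 ± 0.19), and 19 did not pass. Their mean of -0.57 had adjusted p = 7.71e-11, and adjusted p = 0.43 with an estimated correlation. Of 17 skeletal muscle genes, 2 rose (2 adjusted over the list alone), among them Tnnt3 (0.47 ± 0.06), 0 fell and 15 did not pass. Averaging 0.16, they had adjusted p = 0.00994, and adjusted p = 0.43 with an estimated correlation. Of the 14 lists that passed, contractile and smooth muscle, epithelial, one-carbon and serine metabolism, cell cycle and interferon response lost their call both without some array and with an estimated correlation, and are given here by name alone.

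Of 77 oxidative phosphorylation genes, 12 rose (15 adjusted over the list alone), among them Cox5a (0.67 ± 0.09) and Ndufb6 (0.35 ± 0.06), 1 fell and 64 did not pass. Their mean of 0.13 had adjusted p = 2.31e-09, and adjusted p = 0.148 with an estimated correlation. Of 18 TCA cycle and pyruvate dehydrogenase genes, 6 rose (9 adjusted over the list alone), among them Idh2 (0.44 ± 0.06), 0 fell and 12 did not pass. Averaging 0.19, they had adjusted p = 2.42e-05, and adjusted p = 0.304 with an estimated correlation. Of 18 fatty acid oxidation genes, 4 rose (6 adjusted over the list alone), among them Slc25a20 (1.01 ± 0.15) and Hadhb (0.46 ± 0.08), 0 fell and 14 did not pass. Their mean of 0.14 had adjusted p = 0.0137, and adjusted p = 0.43 with an estimated correlation. Of 23 glycolysis genes, 10 rose (12 adjusted over the list alone), among them Ldhb (1.17 ± 0.23) and Slc2a3 (1.09 ± 0.16), 2 fell (3 adjusted over the list alone) and 11 did not pass. Averaging 0.41, they had adjusted p = 0.000164, and adjusted p = 0.43 with an estimated correlation. Of 18 hypoxia response genes, 4 rose (9 adjusted over the list alone), 0 fell and 14 did not pass. Their mean of 0.62 had adjusted p = 2.42e-05, and adjusted p = 0.43 with an estimated correlation. The hypoxia response mean was -0.033, 0.71 and 1.17 in numbers 1, 2 and 3.

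OSKZE against OSKE gave the effect of Zic3 where Esrrb was present. Zic3 raised the epithelial factor Grhl3 (3.51 ± 0.31, adjusted p = 5.9e-06) and Slc38a5 (3.43 ± 0.5), Pglyrp1 (3.32 ± 0.26), Notum (2.99 ± 0.18) and Pls1 (2.95 ± 0.28). The pluripotency genes Nanog (2.91 ± 0.56), Sall4 (2.31 ± 0.49) and Epcam (2.73 ± 0.62) rose, and the glucose carriers Slc2a1 (2.15 ± 0.22) and Slc2a3 (2 ± 0.16) did so too. Csn1s1 (-3.6 ± 0.5), Akr1c18 (-2.37 ± 0.35) and Hbb-y (-2.25 ± 0.26) fell, as they had in OSKZ against OSK, and the collagen genes Col1a2 (-1.32 ± 0.12) and Col1a1 (-1.14 ± 0.25) fell with them. This comparison had the most calls of all: 4840 of 19939 genes passed limma's test, 2693 higher and 2147 lower, and 7305 genes (36.6%, with 10% by chance) did not overlap between the groups. That count was 3088 with only the arrays of the groups compared.

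Among 30 cell cycle genes, 27 rose (27 adjusted over the list alone), among them Cdc20 (1.07 ± 0.15), Bub1b (0.88 ± 0.11) and Mcm3 (0.84 ± 0.08), 0 fell and 3 did not pass. Averaging 0.57, they had adjusted p = 4.63e-20, and adjusted p = 0.0918 with an estimated correlation. Among 13 one-carbon and serine metabolism genes, 9 rose (10 adjusted over the list alone), among them Shmt1 (0.95 ± 0.07) and Tyms (0.64 ± 0.09), 0 fell and 4 did not pass. Their mean of 0.53 had adjusted p = 1.6e-06, and adjusted p = 0.00591 with an estimated correlation. Serine and glycine enzymes of this kind feed nucleotide synthesis, and theirs was the only list call here that held with an estimated correlation, though not with the block as well (adjusted p = 0.087). Among 36 naive pluripotency genes, 15 rose (18 adjusted over the list alone), among them Nanog (2.91 ± 0.56) and Sall4 (2.31 ± 0.49), 1 fell and 20 did not pass. Averaging 0.81, they had adjusted p = 5.76e-05, and adjusted p = 0.647 with an estimated correlation. Among 33 epithelial genes, 10 rose (10 adjusted over the list alone), among them Epcam (2.73 ± 0.62) and Elf3 (2.27 ± 0.39), 0 fell and 23 did not pass. Their mean of 0.7 had adjusted p = 5.76e-05, and adjusted p = 0.647 with an estimated correlation. Among 38 fibroblast and mesenchymal genes, 19 fell (23 adjusted over the list alone), among them Col1a2 (-1.32 ± 0.12) and Col1a1 (-1.14 ± 0.25), 1 rose, Meox1 (1.41 ± 0.19), and 18 did not pass. Averaging -0.48, they had adjusted p = 6.08e-06, and adjusted p = 0.647 with an estimated correlation.

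Among 23 glycolysis genes, 9 rose (10 adjusted over the list alone), among them Slc2a1 (2.15 ± 0.22) and Pfkp (1.43 ± 0.18), 1 fell (2 adjusted over the list alone) and 13 did not pass. Their mean of 0.54 had adjusted p = 8.96e-05, and adjusted p = 0.592 with an estimated correlation. Among 18 hypoxia response genes, 8 rose (11 adjusted over the list alone), among them Ddit4 (0.93 ± 0.16), 0 fell and 10 did not pass. Averaging 0.73, they had adjusted p = 5.76e-05, and adjusted p = 0.592 with an estimated correlation. Among 77 oxidative phosphorylation genes, 15 rose (15 adjusted over the list alone), among them Ndufa4 (0.52 ± 0.11) and Sdhd (0.3 ± 0.06), 0 fell and 62 did not pass. Their mean of 0.096 had adjusted p = 7.87e-05, and adjusted p = 0.292 with an estimated correlation. Among 16 mitochondrial biogenesis regulators, 7 rose (7 adjusted over the list alone), among them Tfam (0.51 ± 0.1) and Tfb1m (0.46 ± 0.08), 0 fell and 9 did not pass. Averaging 0.13, they had adjusted p = 0.0233, and adjusted p = 0.292 with an estimated correlation. Among 18 TCA cycle and pyruvate dehydrogenase genes, 8 rose (8 adjusted over the list alone), among them Suclg2 (0.52 ± 0.1) and Suclg1 (0.45 ± 0.06), 2 fell (3 adjusted over the list alone) and 8 did not pass. Their mean of 0.084 had adjusted p = 0.0319, and adjusted p = 0.592 with an estimated correlation or 0.0725 with the replicate block, and the call was lost without OSKE replicate 1 and OSKZE replicate 2 (adjusted p = 0.309 and 0.051). The replicate block added 2 lists, contractile and smooth muscle (mean -0.37, adjusted p = 0.133, 0.00282 with the block, adjusted p = 0.387 with both) and myeloid (mean -0.29, adjusted p = 0.263, 0.0167 with the block, adjusted p = 0.421 with both).

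The interaction of Zic3 and Esrrb is the difference between OSKZE and OSKE less that between OSKZ and OSK, so a positive value means a greater rise or a smaller fall with Zic3 when Esrrb was present, or a rise in place of a fall. Positive interactions included Pglyrp1 (2.9 ± 0.37, adjusted p = 0.0026), Grhl3 (2.75 ± 0.44, adjusted p = 0.01), Pls1 (2.63 ± 0.4), Trpv5 (2.57 ± 0.23) and Robo4 (2.31 ± 0.15). Negative ones included Col14a1 (-1.57 ± 0.25), Lypd1 (-1.24 ± 0.19), Sfrp1 (-1.23 ± 0.13) and Pde3a (-1.23 ± 0.18). The serine enzyme Shmt1 (0.85 ± 0.1) had a positive interaction as well. In the interaction 191 of 19939 genes passed limma's test, 140 positive and 51 negative. That count was 1623 with the replicate block (835 positive and 788 negative), 104 with only the arrays of the groups compared, 2173 with all 6 arrays of number 1 left out and 291 after quantile normalization. It became 564 without OSKZE replicate 1, 50 without OSK replicate 2, 48 without OSKE replicate 2, 108 without OSKZE replicate 2, 77 without OSK replicate 3, 53 without OSKZ replicate 3, 85 without OSKE replicate 3 and 76 without OSKZE replicate 3. At an unadjusted p under 0.05 there were 2608 genes.

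Of 30 cell cycle genes, 2 had a positive interaction (27 adjusted over the list alone), 0 a negative one and 28 did not pass. Averaging 0.46, they had adjusted p = 1.61e-26, and adjusted p = 0.0371 with an estimated correlation. Of 13 one-carbon and serine metabolism genes, 1 had a positive interaction (3 adjusted over the list alone), namely Shmt1 (0.85 ± 0.1), 0 a negative one and 12 did not pass. Their mean of 0.41 had adjusted p = 9.67e-08, and adjusted p = 0.00271 with an estimated correlation. Both of these calls held with an estimated correlation, and with the block as well the adjusted p was 0.123 for the cell cycle and 0.0471 for the other list. Of 36 naive pluripotency genes, 1 had a positive interaction (3 adjusted over the list alone), 0 a negative one and 35 did not pass. Averaging 0.69, they had adjusted p = 1.88e-06, and adjusted p = 0.631 with an estimated correlation. The 33 epithelial genes, 0 of which passed (3 positive and 0 negative adjusted over the list alone, 11 positive and 0 negative with the block), averaged 0.56 (adjusted p = 4.5e-06, and adjusted p = 0.631 with an estimated correlation). Of 17 trophoblast genes, 1 had a positive interaction (2 adjusted over the list alone), 0 a negative one and 16 did not pass. Averaging 0.41, they had adjusted p = 0.000235, and adjusted p = 0.16 with an estimated correlation.

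Of 38 fibroblast and mesenchymal genes, 2 had a negative interaction (2 adjusted over the list alone), 1 a positive one and 35 did not pass. Their mean of -0.35 had adjusted p = 3.29e-05, and adjusted p = 0.636 with an estimated correlation. Of 18 hypoxia response genes, 1 had a positive interaction (1 adjusted over the list alone), 0 a negative one and 17 did not pass. Averaging 0.53, they had adjusted p = 6.82e-05, and adjusted p = 0.631 with an estimated correlation. Of 23 glycolysis genes, 2 had a positive interaction (2 adjusted over the list alone), 0 a negative one and 21 did not pass. Their mean of 0.26 had adjusted p = 0.00302, and adjusted p = 0.631 with an estimated correlation, and the call was lost without OSKE replicate 1 and OSKZE replicate 3 (adjusted p = 0.0543 and 0.163). The 25 interferon response genes, 0 of which passed (0 adjusted over the list alone), averaged 0.36 (adjusted p = 0.0327, and adjusted p = 0.822 with an estimated correlation), and the call was lost without OSK replicate 1, OSK replicate 2, OSKZ replicate 2, OSKE replicate 2, OSKE replicate 3 and OSKZE replicate 3 (adjusted p = 0.151, 0.25, 0.506, 0.0654, 0.36 and 0.264). By replicate number the hypoxia response mean was -0.042, 0.61 and 1.02, and the interferon response mean -0.61, 1.1 and 0.58. With the block alone, 2 further lists passed, delivered factors (mean 0.44, adjusted p = 0.075, 0.0294 with the block, adjusted p = 0.228 with both) and contractile and smooth muscle (mean -0.32, adjusted p = 0.193, 0.000598 with the block, adjusted p = 0.329 with both).

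The interaction of Zic3 and Nr5a2 was tested in the same way, and Cldn2 (1.58 ± 0.13, adjusted p = 0.00016), a gene of leaky tight junctions, had a positive value. The synaptic gene Syt1 (-0.86 ± 0.09, adjusted p = 0.0017) had a negative one. Here 10 of 19939 genes passed limma's test, 7 positive and 3 negative. That count was 111 with the replicate block (55 positive and 56 negative), 3 with only the arrays of the groups compared, 515 with all 6 arrays of number 1 left out and 5 with the dimmest 33.3% of genes left out. It became 22 without OSK replicate 1, 16 without OSKZ replicate 1 and 20 without OSKN replicate 1. The count at an unadjusted p under 0.05 was 1172.

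The 30 cell cycle genes, 0 of which passed (17 positive and 0 negative adjusted over the list alone), averaged 0.33 (adjusted p = 1.84e-22, and adjusted p = 0.129 with an estimated correlation). The 36 naive pluripotency genes, 0 of which passed (0 adjusted over the list alone, 2 positive and 0 negative with the block), averaged 0.48 (adjusted p = 0.000127, and adjusted p = 0.707 with an estimated correlation). The 18 fatty acid oxidation genes, 0 of which passed (0 adjusted over the list alone), averaged -0.084 (adjusted p = 0.00376, and adjusted p = 0.519 with an estimated correlation). Of the 11 lists that passed, contractile and smooth muscle, epithelial, glycolysis, oxidative phosphorylation, one-carbon and serine metabolism, cholesterol synthesis, neural and skeletal muscle lost their call both without some array and with an estimated correlation, and are given here by name alone. With the block 12 lists passed. Fibroblast and mesenchymal (mean -0.093, adjusted p = 0.0716, 0.00371 with the block, 0.671 with both) was new. Trophoblast (mean 0.17, adjusted p = 0.0716, 0.0285 with the block, 0.579 with both) was too, and not all 11 held. The interferon response list (mean -0.022, adjusted p = 0.737) passed without OSKZN replicate 2 (mean 0.454, adjusted p = 0.0223).

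OSKE against OSKN set the 2 nuclear receptors side by side. Beside the receptors themselves, Ucp1 (4.08 ± 0.45, adjusted p = 6.5e-05), Ceacam2 (3.28 ± 0.7), Tnni3 (3.08 ± 0.36) and Car2 (2.7 ± 0.43) were higher with Esrrb. Cyp11a1 (-3.99 ± 0.26, adjusted p = 4.3e-07), Akr1cl (-3.31 ± 0.2), Adh1 (-3.08 ± 0.15), Pla1a (-2.93 ± 0.15) and Car3 (-2.87 ± 0.28) were lower with Esrrb, that is, higher with Nr5a2, and Cyp11a1, Akr1cl and Adh1 belong to steroid and retinol metabolism. Between the receptors, 2081 of 19939 genes passed limma's test, 988 higher and 1093 lower, and 5563 genes (27.9%, with 10% by chance) did not overlap between the groups. That count was 4607 with the replicate block, 785 with only the arrays of the groups compared and 4234 with all 6 arrays of number 1 left out. It became 1155 without OSKE replicate 2, 931 without OSKN replicate 2 and 1076 without OSKE replicate 3.

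Of 17 contractile and smooth muscle genes, 2 fell (2 adjusted over the list alone), 0 rose and 15 did not pass. Averaging -0.41, they had adjusted p = 0.00388, and adjusted p = 0.998 with an estimated correlation, and the call was lost without OSKN replicate 1 (adjusted p = 0.0702). Of 25 interferon response genes, 2 fell (2 adjusted over the list alone), 0 rose and 23 did not pass. Their mean of -0.69 had adjusted p = 0.000731, and adjusted p = 0.998 with an estimated correlation, and the call was lost without OSKN replicate 1 (adjusted p = 0.0991). Of 13 mesendoderm and primitive streak genes, 1 rose (3 adjusted over the list alone), namely Gsc (0.89 ± 0.14), 0 fell and 12 did not pass. Averaging 0.2, they had adjusted p = 0.0419, and adjusted p = 0.998 with an estimated correlation or 0.0787 with the replicate block, and the call was lost without OSKE replicate 1, OSKN replicate 1 and OSKN replicate 2 (adjusted p = 0.185, 0.0991 and 0.108). With the replicate block alone, the list fibroblast and mesenchymal (mean -0.13, adjusted p = 0.191, 0.0319 with the block, adjusted p = 0.943 with both) passed.

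OSKZE against OSKZN made the same contrast in the presence of Zic3. Ucp1 (3.38 ± 0.45, adjusted p = 0.00028), Car2 (3.05 ± 0.43), Pls1 (3.01 ± 0.28) and Pdk4 (2.49 ± 0.2) were higher with Esrrb, and so was Tfcp2l1 (2.18 ± 0.4). Pdk4 shuts pyruvate dehydrogenase and is a known target of estrogen-related receptors. Pla2g2a (-3.42 ± 0.18, adjusted p = 4.1e-08), Akr1cl (-3.28 ± 0.2), Cyp11a1 (-3.04 ± 0.26) and Adh1 (-3.03 ± 0.15) were lower. With Zic3, 1553 of 19939 genes passed limma's test, 683 higher and 870 lower, and 4312 genes (21.6%, with 10% by chance) did not overlap between the groups. That count was 3454 with the replicate block, 690 with only the arrays of the groups compared and 3918 with all 6 arrays of number 1 left out. It became 835 without OSKZE replicate 2, 858 without OSKZN replicate 2 and 826 without OSKZE replicate 3.

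Among 23 glycolysis genes, 6 rose (14 adjusted over the list alone), among them Pfkp (1.29 ± 0.18) and Pfkm (0.56 ± 0.1), 0 fell and 17 did not pass. Their mean of 0.51 had adjusted p = 1.33e-07, and adjusted p = 0.328 with an estimated correlation. Among 18 hypoxia response genes, 6 rose (11 adjusted over the list alone), 0 fell and 12 did not pass. Averaging 0.71, they had adjusted p = 1.85e-07, and adjusted p = 0.378 with an estimated correlation. Among 77 oxidative phosphorylation genes, 4 rose (3 adjusted over the list alone), 0 fell and 73 did not pass. Their mean of 0.087 had adjusted p = 1.73e-06, and adjusted p = 0.328 with an estimated correlation. Among 18 TCA cycle and pyruvate dehydrogenase genes, 4 rose (5 adjusted over the list alone), 0 fell and 14 did not pass. Averaging 0.14, they had adjusted p = 0.000121, and adjusted p = 0.328 with an estimated correlation. In numbers 1, 2 and 3 the hypoxia response mean was -0.057, 0.92 and 1.26.

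Among 38 fibroblast and mesenchymal genes, 10 fell (17 adjusted over the list alone), among them Tgfbi (-1.06 ± 0.14), 1 rose and 27 did not pass. Their mean of -0.38 had adjusted p = 5.85e-07, and adjusted p = 0.682 with an estimated correlation. Among 21 extraembryonic endoderm genes, 7 fell (8 adjusted over the list alone), among them Cubn (-1.47 ± 0.28), 1 rose and 13 did not pass. Averaging -0.34, they had adjusted p = 0.00392, and adjusted p = 0.328 with an estimated correlation. Among the 10 lists that passed, naive pluripotency, contractile and smooth muscle, epithelial and cell cycle lost their call both without some array and with an estimated correlation, and are given here by name alone.

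The effects of the factors were also compared across the 19939 genes, where genes are not independent replicates. The Esrrb effect without Zic3 and that with Zic3 correlated at r = 0.67 (Spearman rho 0.517), and the Nr5a2 effect at r = 0.763 (rho 0.532). Between the receptors, without shared arrays, the Esrrb effect without Zic3 and the Nr5a2 effect with Zic3 correlated at r = 0.433 (rho 0.394), and at r = 0.396 without OSKZN replicate 2. The Esrrb effect with Zic3 and the Nr5a2 effect without it correlated at r = 0.274 (rho 0.189). Measured against the same OSK arrays, both receptor effects correlated at r = 0.472 (rho 0.367) with a covariance of 0.0442. Unchanged groups that shared controls, simulated 100 times, gave r = 0.503 and a covariance of 0.0113, or 0.00492 with the spread left after the replicate block (r = 0.5). In OSKE and OSKN, 291 genes rose in both (chance 46), 347 fell in both (chance 39) and 25 went opposite ways. In OSKZ and OSKE, 33 rose in both (chance 23), 118 fell in both (chance 22) and 105 went opposite ways. The 3 OSK arrays could not be split between comparisons, so part of the excess may come from the shared controls.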

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

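The comparison of Esrrb between OSKZE and OSKE, the residual shuffles and the fit without number 1 were chosen after the result was seen. The interactions stand here because genes passed limma's test of the difference between the effects of Zic3 with and without a nuclear receptor. With Esrrb, 191 genes passed. Genes that passed whichever array was left out were Pglyrp1 2.9 ± 0.37, Grhl3 2.75 ± 0.44, Pls1 2.63 ± 0.4, Trpv5 2.57 ± 0.23, Robo4 2.31 ± 0.15, Col14a1 -1.57 ± 0.25, Lypd1 -1.24 ± 0.19, Pde3a -1.23 ± 0.18 and Sfrp1 -1.23 ± 0.13. Others lost their calls: Tfap2c 2.04 ± 0.46 (without any of 11 arrays, all but OSKZE replicate 1, adjusted p between 0.0676 and 0.115), Steap1 1.94 ± 0.4 (without any of 8 arrays, all but OSK replicate 1, OSK replicate 3, OSKZ replicate 1 and OSKZE replicate 1, adjusted p between 0.0539 and 0.103), Susd2 1.89 ± 0.36 (without OSKZ replicate 2, OSKE replicate 2, OSKZE replicate 2, OSK replicate 3, OSKZ replicate 3 and OSKZE replicate 3, adjusted p between 0.0562 and 0.0795), Hapln1 -2 ± 0.41 (without any of 8 arrays, all but OSK replicate 1, OSKZ replicate 2, OSKE replicate 3 and OSKZE replicate 1, adjusted p between 0.054 and 0.0939), Parm1 -1.35 ± 0.24 (without OSKE replicate 2, OSK replicate 3 and OSKZ replicate 3, adjusted p between 0.0503 and 0.0577), Mctp1 -1.3 ± 0.28 (without any of 10 arrays, all but OSK replicate 1 and OSKZE replicate 1, adjusted p between 0.0562 and 0.125) and Dach1 -1.29 ± 0.27 (without any of 9 arrays, all but OSKZ replicate 1, OSKE replicate 1 and OSKZE replicate 1, adjusted p between 0.059 and 0.109).

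List means of this interaction that passed at the preset correlation were naive pluripotency 0.69, fibroblast and mesenchymal -0.35, epithelial 0.56, glycolysis 0.26, one-carbon and serine metabolism 0.41, hypoxia response 0.53, cell cycle 0.46, interferon response 0.36 and trophoblast 0.41. With an estimated correlation the cell cycle (adjusted p = 0.0371) and one-carbon and serine metabolism (adjusted p = 0.00271) means passed (adjusted p = 0.123 and 0.0471 with the block as well, where the cell cycle call was lost), and the others had an adjusted p of 0.16 or more. Leaving out OSKE replicate 1 or OSKZE replicate 3 ended the glycolysis call (adjusted p = 0.0543 and 0.163), and the interferon response call ended without OSK replicate 1, OSK replicate 2, OSKZ replicate 2, OSKE replicate 2, OSKE replicate 3 and OSKZE replicate 3 (adjusted p = 0.151, 0.25, 0.506, 0.0654, 0.36 and 0.264).

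With Nr5a2, 10 genes passed the interaction test. Those that passed whichever array was left out were Serpinb11 2.25 ± 0.27, Cldn2 1.58 ± 0.13, Glb1l2 0.93 ± 0.11, Cntnap2 0.92 ± 0.12, Kcnk3 -0.96 ± 0.12, Syt1 -0.86 ± 0.09 and Oxtr -0.75 ± 0.1, of which Cldn2 and Syt1 also passed with only the arrays of the 4 groups, while the adjusted p of the others lay between 0.0552 and 0.0907. The remaining genes were Pde2a 1.7 ± 0.25 (without OSK replicate 2, OSKZ replicate 2, OSKN replicate 2, OSKZ replicate 3 and OSKN replicate 3, adjusted p between 0.0579 and 0.0693), Them6 1 ± 0.16 (without any of 10 arrays, all but OSKZ replicate 1 and OSKN replicate 1, adjusted p between 0.0604 and 0.145) and Itprid1 0.77 ± 0.13 (without any of 10 arrays, all but OSK replicate 1 and OSK replicate 3, adjusted p between 0.0664 and 0.162). List means that passed at the preset correlation were naive pluripotency 0.48, contractile and smooth muscle -0.29, epithelial 0.27, glycolysis -0.19, oxidative phosphorylation -0.034, fatty acid oxidation -0.084, one-carbon and serine metabolism 0.14, cholesterol synthesis -0.086, cell cycle 0.33, neural 0.12 and skeletal muscle 0.0898, and with an estimated correlation each had an adjusted p between 0.129 and 0.772. Of these, leaving out 1 array ended every call but those of naive pluripotency, fatty acid oxidation and the cell cycle, with adjusted p = 0.39, 0.053 and 0.102 for contractile and smooth muscle (without OSKZ replicate 1, OSKN replicate 1 and OSK replicate 3), 0.284, 0.0836, 0.0806 and 0.401 for epithelial (without OSKZ replicate 1, OSKN replicate 1, OSK replicate 3 and OSKZN replicate 3), 0.051 for glycolysis (without OSK replicate 1), 0.08, 0.0562, 0.0501 and 0.0806 for oxidative phosphorylation (without OSKZ replicate 1, OSKN replicate 2, OSKZN replicate 2 and OSK replicate 3), 0.0578, 0.0662 and 0.105 for one-carbon and serine metabolism (without OSK replicate 1, OSKZ replicate 3 and OSKN replicate 3), 0.0783, 0.395, 0.15, 0.361, 0.105 and 0.348 for cholesterol synthesis (without OSK replicate 1, OSKZ replicate 1, OSKN replicate 1, OSKZN replicate 2, OSK replicate 3 and OSKZN replicate 3), 0.12, 0.0559, 0.0525, 0.0782, 0.179, 0.0767, 0.0653 and 0.116 for neural (without OSK replicate 1, OSKZ replicate 1, OSKN replicate 1, OSKZ replicate 2, OSKN replicate 2, OSKZN replicate 2, OSK replicate 3 and OSKZN replicate 3) and 0.142, 0.07, 0.125, 0.37, 0.153, 0.105, 0.0895 and 0.0523 for skeletal muscle (without OSK replicate 1, OSKN replicate 1, OSKZ replicate 2, OSKN replicate 2, OSKZN replicate 2, OSK replicate 3, OSKZ replicate 3 and OSKZN replicate 3).

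The interaction of Zic3 and Esrrb was weighed against technical explanations. After quantile normalization the called genes kept 99.3% of their median signed estimate (0.73 before, 0.725 after). This argues against compressed OSKE values behind that size. Calls rose from 140 positive and 51 negative to 199 and 92, so an effect on them stays open. The Esrrb reading of OSKZE less that of OSKE was 0.044 (0.09, -0.05 and 0.09 in the pairs, 95% interval -0.15 to 0.24), which argues against a rise of over 0.5 in Esrrb RNA. The error shared by all groups, which takes in the spread of OSKZN, gave a wider interval of -0.78 to 0.87, or -0.55 to 0.64 with the block. Among 100 random splits of the 12 arrays, 3 gave as many genes, the real one included (highest other 2173), and within replicate numbers 8 of 100 (highest 3667). Such splits carry the effects of both factors into the contrast and say nothing of chance. With those effects taken out, 5 of 100 shuffles of the residuals gave as many (highest other 1118, pointing to a structure of the samples). Within numbers 2 of 100 did (highest 417), and only this share lay under 0.05. The interaction tests a departure from additive effects, whose cause was not tested.

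For the interaction of Zic3 and Nr5a2, 6 of 100 splits gave as many genes as the real 10 (highest other 1881), and 7 of 100 within replicate numbers (highest 402), with the same fault. Shuffles of the residuals gave as many in 4 of 100 (highest other 1163, again a structure of the samples). Within numbers 1 of 100 did, the real order (highest other 1), a share under 0.05 in a test chosen afterwards. In each comparison of 3 arrays with 3, 10 splits cannot give a share under 0.05, and in each the real split, 1 of 10, was the only one to give as many genes. The real counts were 841 for OSKZ vs OSK, 2160 for OSKE vs OSK, 1580 for OSKN vs OSK, 4559 for OSKZE vs OSK, 2748 for OSKZN vs OSK, 2423 for OSKZE vs OSKZ, 4840 for OSKZE vs OSKE, 2081 for OSKE vs OSKN and 1553 for OSKZE vs OSKZN, against a highest other of 0 in all but OSKE vs OSK (1) and OSKZE vs OSKZN (8), whose highest splits parted 1 of the 3 pairs instead of all 3.

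Probes without a single gene name, which no comparison used, also responded. Of 7067 such probes, 67 passed in OSKZ against OSK, 232 in OSKE, 159 in OSKN, 559 in OSKZE and 256 in OSKZN. In OSKZE 385 were higher and 174 lower, 7.91% of these probes against 21.9% of named genes. They were tested in the fit of all probes, and which genes they read is not given in the sources used here.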

How the results depend on the processing

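The fit without number 1 and the list test with block and estimated correlation were chosen after the result was seen. Gene counts moved with the pairing. The block takes the spread between numbers out of the error, and leaving out number 1 removes the one set apart. With the replicate block the counts were 2533 for OSKZ vs OSK, 4398 for OSKE vs OSK, 3413 for OSKN vs OSK, 6717 for OSKZE vs OSK, 4972 for OSKZN vs OSK, 4678 for OSKZE vs OSKZ, 7135 for OSKZE vs OSKE, 4607 for OSKE vs OSKN, 3454 for OSKZE vs OSKZN, 1623 for the interaction of Zic3 and Esrrb and 111 for the interaction of Zic3 and Nr5a2. Without the 6 arrays of number 1 they were 2616 for OSKZ vs OSK, 4364 for OSKE vs OSK, 4070 for OSKN vs OSK, 5080 for OSKZN vs OSK, 5220 for OSKZE vs OSKZ, 4234 for OSKE vs OSKN, 3918 for OSKZE vs OSKZN, 2173 for the interaction of Zic3 and Esrrb and 515 for the interaction of Zic3 and Nr5a2. With only the arrays of the groups compared, which lowers the degrees of freedom, they were 459 for OSKZ vs OSK, 1238 for OSKE vs OSK, 1048 for OSKN vs OSK, 903 for OSKZE vs OSKZ, 3088 for OSKZE vs OSKE, 785 for OSKE vs OSKN, 690 for OSKZE vs OSKZN, 104 for the interaction of Zic3 and Esrrb and 3 for the interaction of Zic3 and Nr5a2. Quantile normalization gave 291 for the interaction with Esrrb, leaving out the dimmest genes 5 for that with Nr5a2, and the cause was not tested. With 1 array left out, counts ran from 304 (without OSKZ replicate 3) to 997 (without OSKZ replicate 1) for OSKZ vs OSK, from 1037 (without OSK replicate 2) to 2325 (without OSKE replicate 1) for OSKE vs OSK, from 827 (without OSK replicate 2) to 1675 (without OSKN replicate 1) for OSKN vs OSK, from 1468 (without OSKZN replicate 3) to 2926 (without OSKZN replicate 1) for OSKZN vs OSK, from 1130 (without OSKZE replicate 2) to 3287 (without OSKZE replicate 1) for OSKZE vs OSKZ, from 931 (without OSKN replicate 2) to 2685 (without OSKN replicate 3) for OSKE vs OSKN, from 826 (without OSKZE replicate 3) to 2203 (without OSKZE replicate 1) for OSKZE vs OSKZN, from 48 (without OSKE replicate 2) to 564 (without OSKZE replicate 1) for the interaction of Zic3 and Esrrb and from 7 (without OSK replicate 2) to 22 (without OSK replicate 1) for the interaction of Zic3 and Nr5a2. The correlation of the Esrrb effect without Zic3 and the Nr5a2 effect with it ran from 0.396 without OSKZN replicate 2 to 0.435 without OSKZN replicate 1, and the interferon response mean of the interaction of Zic3 and Nr5a2 from -0.425 without OSKZN replicate 1 to 0.454 without OSKZN replicate 2, where it passed. Counts for OSKZE vs OSK and OSKZE vs OSKE moved by less than 1.5 times in every other setting. List calls were lost in 90 cases with an estimated correlation, in 93 with the block as well, in 38 without some array, in 16 without the dimmest genes, in 11 without number 1, in 9 after quantile normalization, in 5 with only the arrays compared and in 4 with the block. Among named genes, 263 calls (per comparison) were lost without some array and 250 with only the arrays compared.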

Other observations

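Of the tests in this part, those of lower delivery and myeloid genes in number 1 were chosen after the result was seen. Of the endothelial genes, Kdr, the receptor of VEGF, rose with Esrrb (1.39 ± 0.16 in OSKE vs OSK, 1.61 ± 0.16 in OSKZE vs OSK and 1.52 ± 0.16 in OSKZE vs OSKZ) and, without it, in OSKZN vs OSK (0.61 ± 0.16, lost without OSK replicate 3 and OSKZN replicate 3, adjusted p = 0.0749 and 0.0823), and the junction gene Esam rose with Zic3 (1.37 ± 0.11 in OSKZ vs OSK, 2.64 ± 0.11 in OSKZE vs OSK, 1.35 ± 0.11 in OSKZN vs OSK and 2.48 ± 0.11 in OSKZE vs OSKE), while Tek fell in OSKZ, OSKZE and OSKZN (-1.14 ± 0.15, -1.57 ± 0.15 and -1.07 ± 0.15). The list as a whole passed in 0 of the 11 comparisons (adjusted p = 0.672 in OSKZE vs OSK, lowest 0.13).

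Fas and Il6 of the p53 and senescence list fell in OSKZE (-1.57 ± 0.23 and -1.3 ± 0.18) and Plk2 rose in OSKN (1.12 ± 0.15). Lpl, an adipocyte gene, fell in OSKZE (-1.14 ± 0.19), and the cartilage collagen Col2a1 fell (-0.59 ± 0.1). In OSKZE vs OSK the list means were -0.16 for p53 and senescence (2 rose and 5 fell of 20, adjusted p = 0.144, lowest of the 11 comparisons 0.0725), -0.13 for adipocyte (0 rose and 2 fell of 11, adjusted p = 0.415, lowest of the 11 comparisons 0.3), 0.055 for keratinocyte (1 rose and 2 fell of 15, adjusted p = 0.732, lowest of the 11 comparisons 0.402) and -0.097 for cartilage and bone (0 rose and 2 fell of 14, adjusted p = 0.457, lowest of the 11 comparisons 0.075). These lists passed in 0 of the 11 comparisons by camera of limma. The mean over a list and its median differed in sign only in lists that did not pass.

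The lower cell cycle genes in OSKE and OSKN than in OSK were weighed against 2 technical explanations. Among 10000 random lists matched on expression, 0% had a median as low in either group, the list medians being -0.374 in OSKE and -0.386 in OSKN against lowest matched medians of -0.181 and -0.151, which argues against a shift of all genes of like expression. After quantile normalization 92.8% of the mean was kept in OSKE and 99.9% in OSKN, which argues against compressed values in these arrays. With an estimated correlation between genes the list had adjusted p = 0.154 in OSKE and 0.226 in OSKN, and part of the change may be shared through the same OSK arrays. A biological effect of the receptors on division was not tested.

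Replicate number 1 stood apart in every group. The readings of Pou5f1, Klf4, Esrrb and Nr5a2 where delivered were lower in number 1 than in both others in 15 of 16 cases, all but Klf4 in OSKN (mean differences -0.41, -0.12, -0.37 and -0.3), so lower delivery of the factors stays open. Of 17 myeloid genes, 15 averaged higher in number 1 (median 0.494, quartiles 0.122 and 0.85), with Lyz2 at 10.51, 8.22 and 8.49 in numbers 1, 2 and 3 and the interferon gene Cxcl10 at 10.48, 8.18 and 8.64, so more myeloid cells in number 1 stay open too. The tie within numbers did not rest on sex chromosomes alone (median correlation 0.533 over 19103 autosomal genes) or compressed values (0.547 after quantile normalization). Xist (11.66 in number 1, 5.87 in 2 and 3) and Eif2s3y (5.51, 10.09 and 10.08) argue against a source of cells shared with number 1. They do not part 2 from 3. Number 1 read as female. The labels give neither day nor preparation.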
